A study of Mus musculus with 24 samples.

How the data were processed

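The counts analysed here were those deposited by the authors: integer read counts per gene, 1 column per library, for 24 libraries. Per the submitters' processing notes, ear reads passed bcl2fastq 1.8.4 and Trimmomatic, graft reads passed FastQC and Trimmomatic, and reads were placed on the mouse genome mm10. The aligner, the counting program, the annotation release and the strand of the reads were not given in the sources used here. With the strand not given, counts of genes that overlap on opposite strands were uncertain, as were counts of near-identical families such as Krtap, Sprr, Stfa and Hba. Per the labels' protocols, whole ear samples and grafts were snap frozen, RNA was extracted with Trizol and Qiagen RNeasy columns, and libraries were made from total RNA with the TruSeq RNA v2 kit. Library type, tissue, donor, recipient and day were taken from the labels, and "dpg" was read as days after grafting.

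Rows were Entrez gene identifiers, and 1 further row held reads of the human papillomavirus 16 E7 transgene. Of 27180 rows, 25275 matched the mouse gene reference and received its symbol and GRCm38 (mm10) position, and 1905 did not match and held 0.826 to 1.56% of the counts of a library. Library totals were 6550011 to 13814448 counts. Mitochondrial genes held 1.485 to 3.386% of the counts and the 10 highest genes 5.315 to 12.652%. A group was read as absent of a gene when it had 0 counts, and the smallest level read as present was 3 counts over the group, so that 3 counts in a single library equalled 0.217 to 0.458 CPM. Where a group had 0 counts its fold was computed from 3 counts over the group and written as "at least"; where it had 1 to 3 counts only CPM values were given. Neither these floors nor the standard errors (SE) covered any error beyond counting and between-library error.

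Genes were tested with edgeR 4.0.16 in R 4.3.3 with limma 3.58.1: filterByExpr by group (minimum count 10, minimum total 15), TMM normalization, robust quasi-likelihood fits and F tests, and Benjamini-Hochberg adjustment over the genes of a comparison. A gene passed the threshold at adjusted p < 0.05 with no fold limit, and "rose" or "fell" was written only for genes that passed. The 6 ear libraries were fitted together (15720 genes, biological coefficient of variation 0.0845), as were the 18 graft libraries (16189 genes, 0.1495), and all 24 libraries were fitted together for differences between graft and ear (16612 genes, 0.1345). Differences between days and between graft and ear were tested as contrasts in these fits. CPM values were counts over TMM-scaled library sizes and were given as mean ± standard deviation (SD) of 3 libraries (6 for both days together). Log2 fold changes were those of the quasi-likelihood fits at the default prior count of edgeR. A prior count of 2 was used for log2 CPM values only. The SE of a log2 fold change was its absolute value over the square root of its F statistic. This SE was derived from the test, and may be too small where a group had few counts. Per-library figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

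Gene lists were written from general knowledge before the data were examined and tested with camera at its preset correlation of 0.01, with a list of at least 3 measured genes required. The 33 lists tested were DNA replication and E2F target, mitosis, p53 target, wound-associated epidermal, cornified envelope, basal keratinocyte, hair follicle, sebaceous gland, melanocyte, dermal matrix, matrix-remodelling protease, adipocyte, skeletal muscle, cartilage, endothelial, Schwann cell, erythroid, T cell, cytotoxic lymphocyte, NKT cell-associated, immune regulatory, IL-17 and acute inflammation, type 2 cytokine, interferon response, antigen presentation, macrophage and monocyte, neutrophil, dendritic and Langerhans cell, mast cell, B and plasma cell, hypoxia response, oxidative phosphorylation, and immediate early and heat shock genes. A sex-linked list was checked by its genes, as Xist alone of it was tested. Each list was also tested with a correlation estimated from the residuals, and its members were adjusted over the list alone as well as over all genes.

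Genes were named by a fixed rule. A panel of Cd1d1, Cdkn2a, Mki67, Ifng, Ido1 and Arg1 was given in each comparison. To it were added the 6 rising and 6 falling genes with the largest log2 fold changes among genes past the threshold with at least 1 CPM in the higher group, no overlap between the libraries of the groups (not required for differences of differences) and a symbol other than a predicted or Riken one. Up to 8 lists with the largest share of members past the threshold then gave up to 3 members each, by smallest adjusted p, to at most 30 genes per comparison.

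The alternatives were RLE and upper quartile normalization, no low-count filter, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, a log2 fold change of at least 1, fits of only the groups compared, all 24 libraries in 1 fit for the ear, each library left out in turn, the replicate number as a block, and for lists the estimated correlation and fry. The replicate numbers of the labels were not treated as pairs, because residual correlations of same-numbered libraries were -0.348 to 0.291 (median 0.024, 45 pairs). Under upper quartile normalization the median log2 fold change of all ear genes moved from 0.002 to -0.118, and that of the difference between 14 dpg grafts and ear from -0.045 to 0.062.

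The test was tested on simulated data for 6 comparisons, with 200 genes changed. They were made from 1 mean per gene over all libraries of the fit and from the fitted dispersions, with genes drawn independently. At folds of 1.5, 2 and 4 the share found was 68.7, 91 and 98.5% in the ear, 29.9, 70.1 and 92.4% for E7 against C57BL/6 grafts at 14 dpg, and 43.3, 61.2 and 95.5% for CD1dKOxE7 against E7 grafts at 28 dpg. It was 64.2, 85.1 and 95.5% over both days, 19.4, 55.2 and 72.7% for the difference of the CD1dKO effect between days, and 25.4, 59.7 and 87.9% for the difference between graft and ear. False calls numbered 29 in the simulated ear, 14.4% of its calls, and 7 for the difference of the CD1dKO effect between days (6.7%), both above the nominal 5%, and were 1.5 to 3.6% of calls elsewhere. With DESeq2 they were 9.4 to 14.9% of calls, and 10.1% for CD1dKOxE7 against E7 grafts at 28 dpg. The changed list of 20 genes was recovered in all 6 fits. These data held far fewer changed genes than most real comparisons and no correlation between genes. The shares of false calls and the recovery of lists therefore apply to such data only.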

Results

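Gene expression was compared in mouse skin that carries the human papillomavirus 16 E7 oncoprotein behind the keratin 14 promoter (K14E7, here E7), in E7 skin of donors labelled CD1d-/- (CD1dKOxE7), and in C57BL/6 skin (C57). CD1d presents lipids to natural killer T (NKT) cells. Ear skin of C57 and E7 mice was sequenced at 8 weeks of age. Skin of C57, E7 and CD1dKOxE7 donors grafted onto C57 recipients was sequenced at 14 and 28 days after grafting (dpg). With 3 libraries in each of 8 groups there were 24 libraries, 6 of ear and 18 of grafts. Levels below are CPM (counts scaled to a common library total) as mean ± SD of the 3 libraries of a group, and log2 fold changes are given ± SE. Ear and graft libraries were sequenced on different flow cells, and CD1dKOxE7 grafts on another lane than C57 and E7 grafts, so that tissue and donor differences could not be separated from these.

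Reads of the E7 transgene followed the donor labels. E7 reached 51.1 ± 7.92 CPM in E7 ear, 36.7 ± 3.70 CPM in E7 grafts at 14 dpg and 28.9 ± 4.61 CPM at 28 dpg, against 0 to 2 counts in any C57 library. At 14 dpg the CD1dKOxE7 grafts held 20.3, 17.6 and 23.2 CPM of E7, each lower than every E7 graft of that day (32.6, 39.8 and 37.8 CPM). At 28 dpg they held 44.6, 44.6 and 18.8 CPM, 2 above and replicate 3 below every E7 graft of that day. Cd1d1 (Entrez 12479, chromosome 3), the CD1d gene, was read in every group. In CD1dKOxE7 grafts it stood at 13.5, 17.3 and 11.3 CPM at 14 dpg and at 5.40, 4.46 and 14.7 CPM at 28 dpg, against 15.0 ± 1.24 and 23.4 ± 2.25 CPM in E7 grafts and 15.6 ± 0.366 and 21.7 ± 6.24 CPM in C57 grafts. The deleted part of the gene was not given in the sources used here, so these grafts are called by their label. Xist, read from the inactive X chromosome, was read in all libraries, as in females.

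**Figure D1:**
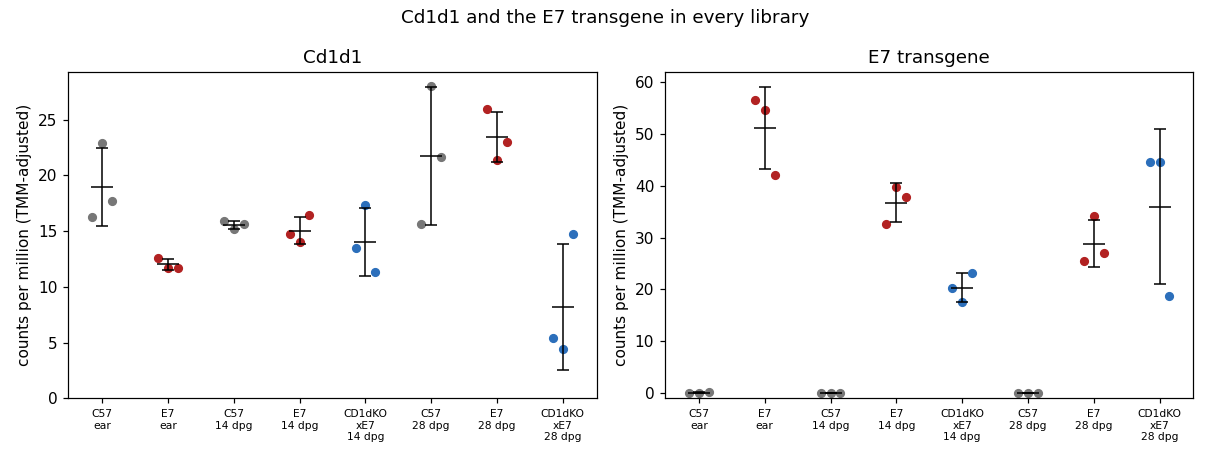
CPM of Cd1d1 and of the E7 transgene in each of the 24 libraries, by group, with points for libraries and bars for mean ± SD. E7 separates the donors labelled C57 from all others, whereas Cd1d1 is read in CD1dKOxE7 grafts, lowest in 2 of the 3 at 28 dpg.

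Ear skin of E7 mice carried far more transcript of the cell cycle than C57 ear. Mki67, a marker of proliferating cells, rose from 103 ± 24.8 to 823 ± 53 CPM (log2 fold change 3.05 ± 0.16, adjusted p = 1.80e-06), and Cdkn2a, which encodes the inhibitor p16 and ARF, rose 71.2-fold from 0.103 ± 0.0906 to 7.77 ± 1.21 CPM (6.15 ± 0.39, adjusted p = 2.14e-07). Rrm2, a subunit of ribonucleotide reductase, rose 14.0-fold to 219 ± 8.36 CPM (3.80 ± 0.09), E2f8 rose 7.57-fold (2.92 ± 0.08) and the replicative helicase gene Mcm4 rose 4.03-fold to 169 CPM. All 46 DNA replication and E2F target genes rose (median log2 fold change 2.05, adjusted p = 8.32e-68), and the list stayed past the threshold with an estimated correlation (adjusted p = 0.0463). All 30 mitosis genes rose as well (median 2.57, adjusted p = 5.34e-41; adjusted p = 0.159 with an estimated correlation). They included Cdk1 (7.00-fold), the anaphase activator Cdc20 (7.45-fold) and the spindle checkpoint kinase gene Bub1b (4.17-fold). Of 16 p53 target genes, 12 rose and 1 fell (adjusted p = 8.93e-06; adjusted p = 0.0613 with an estimated correlation).

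The epidermal program of E7 ear was shifted toward the cornified layers and toward wound keratins. Filaggrin (Flg) rose 9.86-fold, from 193 ± 17.5 to 1828 ± 254 CPM (3.30 ± 0.12, adjusted p = 5.04e-09), the terminal differentiation protease gene Casp14 rose 8.21-fold to 421 CPM (3.04 ± 0.09), and involucrin (Ivl) rose 4.95-fold to 402 CPM (2.31 ± 0.06). Of 33 cornified envelope genes, 32 rose and 1 fell (median 1.39, adjusted p = 1.30e-22; adjusted p = 0.0613 with an estimated correlation). Wound-associated epidermal genes rose too (16 of 18, 1 fell, median 3.15, adjusted p = 8.09e-20; adjusted p = 0.159 with an estimated correlation). Basal keratinocyte genes went lower, 3 rising and 8 falling of 14 (median -0.57, adjusted p = 0.0223; adjusted p = 0.518 with an estimated correlation). Among the largest rises were the natriuretic peptide gene Nppb (184-fold, 7.53 ± 0.26), the protease inhibitor gene Spink7 (166-fold, 7.38 ± 0.30, to 30.5 CPM) and the lactoperoxidase gene Lpo (166-fold, 7.37 ± 0.58, to 87.7 ± 38.2 CPM). Adgrg7 stood at 31.7 ± 9.16 against 0.0751 CPM and the gasdermin gene Gsdmc3 at 5.42 against 0.0235 CPM, which lost its call without the highest-numbered C57 ear library (adjusted p = 0.0882). Hair follicle genes (7 rose and 2 fell of 14, adjusted p = 0.239) and sebaceous gland genes (4 and 2 of 12, adjusted p = 0.656) did not pass as lists.

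Transcripts of the dermis, fat, muscle and nerve made up less of the E7 ear. Dermal matrix genes fell (21 of 23, median -1.26, adjusted p = 2.34e-06; adjusted p = 0.429 with an estimated correlation). Adipocyte genes fell too (14 of 15, 1 rose, median -1.86, adjusted p = 4.03e-09; adjusted p = 0.308 with an estimated correlation). Among the fat genes were lipoprotein lipase (Lpl, 2.07-fold, -1.05 ± 0.06), Car3 (3.72-fold, from 239 to 62.0 CPM) and resistin (Retn, 5.38-fold). All 23 skeletal muscle genes fell (median -1.64, adjusted p = 2.01e-06; adjusted p = 0.499 with an estimated correlation). Cartilage genes did likewise (13 of 14, median -2.00, adjusted p = 1.28e-10; adjusted p = 0.114 with an estimated correlation). The 16 endothelial genes (median -0.87, adjusted p = 1.12e-05; adjusted p = 0.337 with an estimated correlation) and the 10 Schwann cell genes (median -1.79, adjusted p = 3.34e-10; adjusted p = 0.114 with an estimated correlation) all fell. Melanocyte genes fell too (5 of 7, adjusted p = 0.0125; adjusted p = 0.394 with an estimated correlation). Matrix-remodelling protease genes (4 rose and 5 fell of 12, adjusted p = 0.993) and erythroid genes (5 of 5 fell, adjusted p = 0.153) did not pass as lists. The largest falls were those of Ccdc27 (13.0-fold, -3.70 ± 0.40), the vesicle gene Rab3b (12.6-fold, -3.66 ± 0.38), the Mas-related receptor gene Mrgprb3 (12.0-fold, -3.58 ± 0.29), Ifitm6 (10.9-fold, -3.45 ± 0.37) and the hair keratin-associated gene Krtap3-2 (10.8-fold, from 18.8 to 1.66 CPM). The secretoglobin gene Scgb1a1 stood at 0.0325 against 1.86 CPM. Levels were shares of a whole-ear total.

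Interferon, neutrophil and IL-17 genes were higher in E7 ear, whereas T cell genes did not pass as a list. Of 32 interferon response genes 30 rose (median 1.65, adjusted p = 1.53e-22; adjusted p = 0.0613 with an estimated correlation). Antigen presentation genes rose in part (11 of 18, median 0.70, adjusted p = 5.87e-05; adjusted p = 0.429 with an estimated correlation). Neutrophil genes rose (9 of 10, 1 fell, median 4.23, adjusted p = 0.000471; adjusted p = 0.394 with an estimated correlation). IL-17 and acute inflammation genes did so too (8 of 10, 1 fell, median 3.71, adjusted p = 5.87e-05; adjusted p = 0.18 with an estimated correlation), with immune regulatory genes (10 of 15, median 0.90, adjusted p = 0.00437; adjusted p = 0.309 with an estimated correlation). Mast cell genes fell (10 of 14, 1 rose, median -1.11, adjusted p = 0.00423; adjusted p = 0.429 with an estimated correlation). T cell genes (6 rose and 6 fell of 17, adjusted p = 0.94), cytotoxic lymphocyte genes (2 and 4 of 8, adjusted p = 0.94), NKT cell-associated genes (2 and 1 of 3, adjusted p = 0.639) and B and plasma cell genes (1 and 1 of 3, adjusted p = 0.94) did not pass as lists. The same held for macrophage and monocyte genes (5 and 3 of 18, adjusted p = 0.94), dendritic and Langerhans cell genes (5 and 5 of 14, adjusted p = 0.184) and type 2 cytokine genes (5 and 2 of 10, adjusted p = 0.553). Cd1d1 fell from 19.0 ± 3.52 to 12.0 ± 0.492 CPM (-0.60 ± 0.14, adjusted p = 0.00256; 0.0702 with all 24 libraries in one fit), Arg1 did not pass (-0.15 ± 0.42, adjusted p = 0.769), and Ifng and Ido1 were too low to test (0.286 and 0.384 CPM in E7 ear).

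Immediate early and heat shock genes rose in E7 ear (9 of 15, median 0.79, adjusted p = 9.92e-05; adjusted p = 0.306 with an estimated correlation). Hypoxia response genes (6 rose and 2 fell of 14, adjusted p = 0.184) and oxidative phosphorylation genes (4 and 2 of 19, adjusted p = 0.903) did not pass, and their medians, like that of the macrophage list, changed sign under upper quartile normalization. In the ear the counts adjusted over the list alone equalled those over all genes in every list but the macrophage list, where 2 fell adjusted over the list alone. Of 15720 genes, 5129 rose and 5138 fell. For 11151 genes (70.9%, 10% by chance) the libraries of the groups did not overlap. Under upper quartile normalization 39.1% of the changed genes were higher instead of 50%.

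E7 grafts at 14 dpg carried more cell cycle and interferon transcript than C57 grafts of the same day. Mki67 rose from 271 ± 30.1 in C57 grafts to 613 ± 34.3 CPM in E7 grafts (1.19 ± 0.16, adjusted p = 0.000109) and Cdkn2a from 1.46 ± 0.654 to 3.64 ± 0.458 CPM (1.33 ± 0.42, adjusted p = 0.0263). All 46 DNA replication and E2F target genes rose (median 1.33, adjusted p = 1.53e-62; adjusted p = 0.0508 with an estimated correlation). They included the helicase genes Mcm3 (3.32-fold, 1.73 ± 0.12, from 40.1 to 132 CPM) and Mcm4 (1.53 ± 0.11) and the primase gene Prim1 (4.13-fold, 2.04 ± 0.15). All 30 mitosis genes rose (median 0.97, adjusted p = 2.79e-30; adjusted p = 0.114 with an estimated correlation). Top2a (2.18-fold), Birc5 (1.70-fold) and Cenpe (2.40-fold) were part of them. Adjusted over the list alone these counts were again 46 and 30. Of 32 interferon response genes 31 rose, and 32 adjusted over the list alone (median 1.62, adjusted p = 2.25e-34; adjusted p = 0.114 with an estimated correlation). They included Ifih1, a sensor of viral RNA (3.82-fold, 1.93 ± 0.14, from 30.1 to 114 CPM), the antiviral gene Oas1a (4.80-fold, 2.26 ± 0.22) and Irf9 (2.32-fold).

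Immediate early and heat shock genes, which follow tissue handling, were higher in E7 grafts at 14 dpg (9 of 15 rose, 10 adjusted over the list alone, median 0.78, adjusted p = 1.35e-05; adjusted p = 0.47 with an estimated correlation). Cornified envelope genes were higher as well (21 of 33 rose and 1 fell; 23 and 2 adjusted over the list alone; adjusted p = 6.51e-13; adjusted p = 0.185 with an estimated correlation). Wound-associated epidermal genes were higher too (11 of 20 rose and 1 fell; 12 and 1 adjusted over the list alone; adjusted p = 1.22e-06; adjusted p = 0.185 with an estimated correlation). Dermal matrix genes fell (17 of 23, 19 adjusted over the list alone, median -0.86, adjusted p = 6.96e-07; adjusted p = 0.53 with an estimated correlation). Macrophage and monocyte genes mostly fell (13 of 18, 2 rose; 14 and 2 adjusted over the list alone; adjusted p = 0.00135; adjusted p = 0.677 with an estimated correlation). Cd14 fell 2.05-fold (-1.03 ± 0.24), while Ly6c2 (2.53-fold, 1.34 ± 0.29) rose. The largest rises were those of E7 itself (at least 283-fold, 0 counts in C57 grafts), the interferon-induced Apol9a (12.9-fold, from 3.45 to 44.3 CPM), Adgrg7 (12.9-fold, 3.69 ± 0.93) and the activity-regulated Arc (12.5-fold, from 12.4 to 153 CPM). The defensin gene Defb3 stood at 2.11 against 0.0407 CPM and Ankk1 at 2.15 against 0.0815 CPM. The largest falls were those of Krt24 (13.9-fold, -3.80 ± 0.71, from 11.5 to 0.816 CPM), Scgb1b27 (11.0-fold, -3.46 ± 0.55), lubricin (Prg4, 9.20-fold, -3.20 ± 0.69) and the B cell chemokine gene Cxcl13 (8.26-fold, -3.05 ± 0.92). Reg3g and Pax1 stood at 0.0885 CPM in E7 grafts against 1.55 and 1.03 CPM. Leaving out 1 library ended the calls of Cdkn2a (adjusted p = 0.121 without C57 replicate 3, and also without E7 replicate 1 or 3), Cxcl13 (0.0897 without C57 replicate 3, and also without E7 replicate 1 or 2) and Adgrg7 (2.02, adjusted p = 0.0503 without E7 replicate 3). With only the groups compared in the fit Adgrg7 (adjusted p = 0.107) and Prg4 (0.0519) lost theirs. Calls were also lost for Pax1 (adjusted p = 0.0558, 0.0585 and 0.0783 without C57 replicate 2, C57 replicate 3 and E7 replicate 2) and Reg3g (0.0525 and 0.0541 without C57 replicate 1 and E7 replicate 2). Cd1d1 (-0.04 ± 0.32, adjusted p = 0.942), Ifng (1.82 ± 0.90, adjusted p = 0.138), Ido1 (adjusted p = 0.985) and Arg1 (0.16 ± 0.62, adjusted p = 0.865) did not pass. In all, 2555 genes rose and 2334 fell, 4889 of 16189, and 3043 without replicate 3 of the C57 grafts at 14 dpg. For 7645 genes (47.2%, 10% by chance) the libraries of the groups did not overlap.

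At 28 dpg too, cell cycle transcripts were higher in E7 than in C57 grafts, together with sebaceous gland and oxidative phosphorylation genes. Mki67 rose 3.31-fold, from 128 ± 22.1 to 412 ± 33.8 CPM (1.73 ± 0.16, adjusted p = 2.00e-06), and Cdkn2a 2.06-fold to 6.14 ± 1.07 CPM (1.04 ± 0.37, adjusted p = 0.0368). Of the 46 DNA replication and E2F target genes 45 rose, and 46 adjusted over the list alone (median 1.71, adjusted p = 2.00e-72, and adjusted p = 0.0323 with an estimated correlation). Mcm3 (4.46-fold, 2.16 ± 0.12), Mcm4 (3.72-fold) and Mcm5 (6.37-fold, from 22.3 to 138 CPM) were among them. Of 30 mitosis genes 29 rose, and 30 adjusted over the list alone (median 1.48, adjusted p = 0.0393 with an estimated correlation), with Birc5 (2.98-fold), Top2a (3.39-fold) and the spindle factor gene Tpx2 (3.50-fold). Wound-associated epidermal genes rose (13 of 20; 13 rose and 1 fell adjusted over the list alone; median 2.02, adjusted p = 0.0449 with an estimated correlation). Interferon response genes rose (28 of 32, and 28 adjusted over the list alone, median 1.51, adjusted p = 3.27e-23; adjusted p = 0.149 with an estimated correlation), with Oas1a (6.74-fold, from 12.0 to 79.1 CPM), Ifih1 (3.27-fold) and Irf9 (1.25 ± 0.11). Oxidative phosphorylation genes rose (16 of 19, median 0.32, adjusted p = 1.43e-05; adjusted p = 0.149 with an estimated correlation). Sebaceous gland genes rose as well (9 of 12, median 1.25, adjusted p = 0.000221; adjusted p = 0.545 with an estimated correlation).

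All 10 Schwann cell genes fell in E7 grafts at 28 dpg (median -1.30, adjusted p = 1.15e-05; adjusted p = 0.149 with an estimated correlation). The myelin genes Prx (2.32-fold, -1.21 ± 0.22) and Ncmap (2.56-fold, -1.35 ± 0.26) and the cadherin gene Cdh19 (2.46-fold, -1.30 ± 0.22) were part of this. Dermal matrix genes fell (16 of 23, 20 adjusted over the list alone, median -0.88, adjusted p = 4.31e-06; adjusted p = 0.545 with an estimated correlation). Endothelial genes fell too (11 of 16, adjusted p = 0.000127; adjusted p = 0.545 with an estimated correlation). T cell genes (5 of 17 rose, adjusted p = 0.464) and cytotoxic lymphocyte genes (3 of 16 rose, 1 adjusted over the list alone, adjusted p = 0.333) did not pass as lists. Among the largest rises, Chil4, a chitinase-like gene, stood at 33.1 ± 40.7 CPM against 0 counts (at least 284-fold), and E7 was at least 238-fold and the cystatin-like Csta3 at least 15.4-fold higher. Lpo rose 100-fold (6.65 ± 0.39, adjusted p = 6.10e-08) and Sprr2a3 98.3-fold (6.62 ± 0.76, to 394 CPM). Adgrg7 stood at 11.5 against 0.0305 CPM, and Ifng, the interferon gamma gene, at 0.561 against 0.0305 CPM. Ifng lost its call without any 1 of the 6 libraries (adjusted p = 0.0588 to 0.122), Csta3 in 5 of these fits (0.0679 to 0.0924) and Cdkn2a in 4 (0.0812 to 0.128, highest without C57 replicate 2). With only the groups compared in the fit Chil4 (adjusted p = 0.149) and Cdkn2a (0.0754) lost theirs. Gng13 (29.1-fold, -4.87 ± 0.53), Krt24 (21.3-fold, from 149 to 6.77 CPM), the granin gene Scg2 (10.2-fold), Scgb1a1 (9.67-fold), Pls1 (7.98-fold) and Nptx1 (6.70-fold) fell. Cd1d1 (0.16 ± 0.30, adjusted p = 0.714), Ido1 (adjusted p = 0.25) and Arg1 (adjusted p = 0.714) did not pass. In all, 3345 genes rose and 2383 fell (58.4% higher, 47.9% under upper quartile normalization). For 8569 genes (52.9%, 10% by chance) the libraries of the groups did not overlap.

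Over both days, with 6 libraries per group, 8197 genes differed between E7 and C57 grafts, 4212 higher and 3985 lower. Mki67 rose 2.75-fold (1.46 ± 0.11, adjusted p = 1.34e-07), Cdkn2a rose (1.19 ± 0.28, adjusted p = 0.00251) and Ifng rose 6.17-fold (2.62 ± 0.78, adjusted p = 0.0117). E7 was at least 525-fold higher, and Lpo (30.2-fold, 4.92 ± 0.24) and the late cornified envelope gene Lce3d (21.9-fold, 4.45 ± 0.39) rose. Krt2, a keratin of the upper epidermis, fell from 7540 ± 3031 to 1280 ± 692 CPM (5.60-fold, -2.49 ± 0.64, adjusted p = 0.0055), and Wfdc21 (3.95-fold), Mrgprb3 (4.67-fold) and the Schwann cell gene S100b (3.68-fold) fell. All 46 DNA replication and E2F target genes rose (adjusted p = 0.0289 with an estimated correlation). The 30 mitosis genes (adjusted p = 0.0574 with an estimated correlation) and 32 interferon response genes (adjusted p = 0.109 with an estimated correlation) all rose, while 21 of 23 dermal matrix genes fell (adjusted p = 0.578 with an estimated correlation). These 4 counts were unchanged adjusted over the list alone.

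Gene by gene, the E7 difference in grafts followed that in ear at a smaller size. Over 15374 genes the log2 fold changes of ear and of 28 dpg grafts had a Pearson correlation of 0.841 (Spearman 0.827), and those of ear and of 14 dpg grafts 0.733 (Spearman 0.762). Of 10080 genes changed in ear, 92.8% had the same sign in 28 dpg grafts and 90% in 14 dpg grafts, and the median ratio of graft to ear change was 0.59 and 0.51. Rises past the threshold in both ear and 28 dpg grafts numbered 2864 (1094 by independence), and falls 2081 (762 by independence).

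**Figure D2:**
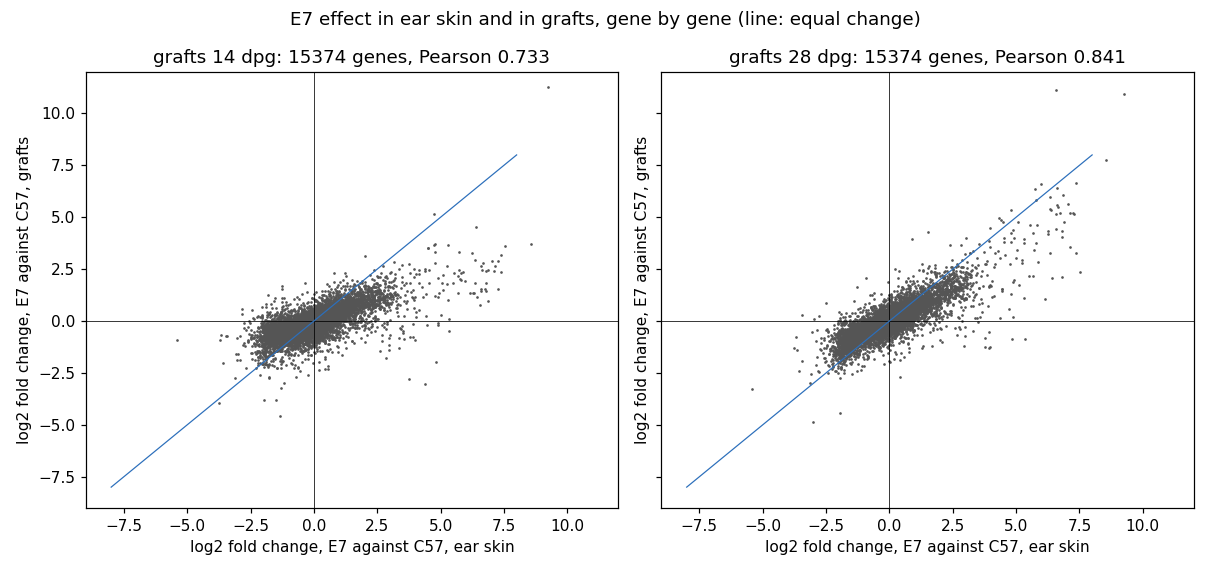
Log2 fold change of E7 against C57 in ear skin (horizontal) and in grafts at 14 and 28 dpg (vertical), with a point per gene over 15374 genes and a line of equal change. Most points lie between the horizontal axis and the line, so changes were smaller in grafts.

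The E7 difference departed between graft and ear in mitosis, neutrophil and wound-associated epidermal genes at 14 dpg. It was smaller than in ear for Mki67 (-1.87 ± 0.23, adjusted p = 2.67e-05), Cdkn2a (-4.79 ± 0.75, adjusted p = 0.000256) and Cdk1 (-1.82 ± 0.18), and 29 of 30 mitosis genes were lower (29 adjusted over the list alone, median -1.67, adjusted p = 0.0158 with an estimated correlation). Neutrophil genes were lower (10 of 15, 12 over the list alone, median -3.58), such as Stfa3 (-4.96 ± 0.52), Stfa1 (-5.14) and Csf3r (-2.43). Wound-associated epidermal genes were too (13 of 20, 14 over the list alone), such as Sprr2h (-4.41), Gjb6 (-3.77) and Krt16 (-3.85). Both had adjusted p = 0.0234 with an estimated correlation. C57 list means were higher in grafts than in ear (neutrophil 3.16 against 0.32, wound 5.37 against 3.07, mitosis 5.05 against 3.79 log2 CPM). E7 means were 3.56 against 3.25, 6.43 against 6 and 5.95 against 6.27. Of the DNA replication and E2F target genes 29 were lower (36 adjusted over the list alone, median -0.72, adjusted p = 1.68e-21; adjusted p = 0.14 with an estimated correlation), such as E2f7 (-2.26 ± 0.28), Mcm10 (-1.37) and Rbl1 (-1.02). Of 16612 genes, 668 were higher and 1430 lower in this difference (31.8% higher, 55.2% under upper quartile normalization), and 1394 were past the threshold without replicate 1 of the C57 grafts at 14 dpg. At 28 dpg, 381 were higher and 853 lower (30.9% higher, 49.0% under upper quartile normalization), with 786 and 787 genes past the threshold without the highest-numbered C57 or E7 ear library and 743 without replicate 1 of the E7 grafts. There the difference was smaller for Mki67 (-1.34 ± 0.23, adjusted p = 0.0019), Cdkn2a (-5.09 ± 0.69, adjusted p = 0.00025), Flg (-1.93 ± 0.33), Casp14 (-1.99 ± 0.32), Ivl (-1.47 ± 0.16) and Cdc20 (-1.62 ± 0.21). Mitosis genes were lower (27 of 30, 29 over the list alone, median -1.06, adjusted p = 2.92e-40). Cornified envelope genes were too (15 of 33, 24 over the list alone, adjusted p = 4.54e-16). So were neutrophil genes (6 of 15, 10 over the list alone, median -2.33, adjusted p = 4.39e-08). With an estimated correlation, their adjusted p was 0.127, 0.13 and 0.13.

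CD1dKOxE7 grafts at 14 dpg carried far more cytotoxic T cell transcript than E7 grafts of the same day. Cd8a rose 38.2-fold, from 1.87 ± 0.290 to 74.9 ± 8.05 CPM (5.26 ± 0.50, adjusted p = 6.72e-06), granzyme B (Gzmb) rose 17.4-fold, from 2.95 ± 1.93 to 53.8 ± 8.88 CPM (4.12 ± 0.33, adjusted p = 1.97e-06), and Ifng rose 10.8-fold, from 0.775 ± 0.457 to 8.78 ± 3.38 CPM (3.43 ± 0.54, adjusted p = 0.000195). All 16 cytotoxic lymphocyte genes rose, also adjusted over the list alone (median 3.45, adjusted p = 4.22e-27, and adjusted p = 0.0167 with an estimated correlation). Xcl1 (14.2-fold, 3.83 ± 0.33) and the NK receptor gene Klrd1 (7.73-fold, 2.95 ± 0.28) belonged to these. Of 17 T cell genes 16 rose, also adjusted over the list alone (median 2.48, adjusted p = 4.86e-25, and adjusted p = 0.0202 with an estimated correlation). Cd3d (8.80-fold, 3.14 ± 0.25), Cd2 (7.32-fold, 2.87 ± 0.25) and the costimulator gene Icos (5.96-fold, from 10.6 to 64.9 CPM) were among them. Of 8 NKT cell-associated genes 7 rose (median 2.93, adjusted p = 0.0309 with an estimated correlation), such as Il2rb (9.91-fold, to 94.9 CPM), Cd160 (9.70-fold, 3.28 ± 0.28) and Klrb1c (7.91-fold, 2.98 ± 0.38), genes that NK and T cells express too. The cytotoxic list stood at 4.23 ± 0.17 log2 CPM in these grafts, against 0.77 ± 0.27 in E7 and 0.45 ± 0.23 in C57 grafts.

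Antigen presentation and its regulators rose with them. All 18 antigen presentation genes rose, also adjusted over the list alone (median 1.85, adjusted p = 9.63e-33, and adjusted p = 0.0202 with an estimated correlation). The class I gene H2-K1 (2.72-fold, from 1246 ± 265 to 3483 ± 307 CPM) and the class II genes H2-Ab1 (4.43-fold, 2.15 ± 0.21) and H2-Aa (4.33-fold, 2.12 ± 0.21) belonged to these. Of 18 immune regulatory genes 15 rose, 17 adjusted over the list alone (median 2.01, adjusted p = 0.0167 with an estimated correlation). Ido1, a tryptophan-degrading enzyme that interferon gamma induces, rose 16.2-fold to 3.62 ± 1.40 CPM (4.02 ± 1.17, adjusted p = 0.0171; 0.0578 and 0.0593 without E7 replicate 1 or 2), while Arg1 did not pass (90.3 ± 65.0 against 32.3 ± 21.2 CPM, 1.43 ± 0.61, adjusted p = 0.0964). Interferon response genes rose (23 of 32, 28 adjusted over the list alone, median 1.10, adjusted p = 6.13e-15; adjusted p = 0.265 with an estimated correlation). Macrophage and monocyte genes followed (15 of 18, median 1.41, adjusted p = 6.65e-09; adjusted p = 0.278 with an estimated correlation). The largest rises included the ubiquitin-like gene Ubd (90.0-fold, 6.49 ± 0.89, to 72.4 ± 23.4 CPM), Trbv12-2, a T cell receptor segment (36.9-fold, 5.21 ± 0.86), and Ccnb1ip1 (4.14 ± 2.14 CPM against 0 counts, at least 32.6-fold). The chemokine gene Ccl1 stood at 7.48 against 0.0359 CPM and the cytokine gene Il21 at 3.52 against 0.0717 CPM, the latter not past the threshold with DESeq2 (adjusted p = 0.361).

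Late epidermal differentiation and proliferation genes were lower in CD1dKOxE7 than in E7 grafts at 14 dpg, while wound and neutrophil genes were higher. Krt2 fell 133-fold, from 1111 ± 428 to 8.51 ± 3.37 CPM (-7.05 ± 1.15, adjusted p = 0.000404), Spink7 15.8-fold from 122 to 8.15 CPM (-3.98 ± 0.44), the neuropeptide gene Nmu 18.1-fold from 15.6 to 0.856 CPM (-4.18 ± 0.33), and Slurp2 7.31-fold (-2.87 ± 0.42). Pyy fell 9.63-fold (-3.27 ± 0.93), but without E7 replicate 3 its change was -1.43 (adjusted p = 0.198), and its call was lost without CD1dKOxE7 replicate 2 or 3 (0.0518 and 0.0519) or with only the groups compared in the fit (0.092). Phex stood at 0.0639 against 1.48 CPM and lost its call without E7 replicate 2 (0.0663) or CD1dKOxE7 replicate 2 or 3 (0.0769 and 0.0567). Of 33 cornified envelope genes 25 fell, 26 adjusted over the list alone (median -1.40, adjusted p = 4.28e-28, and adjusted p = 0.0202 with an estimated correlation). Mki67 fell from 613 ± 34.3 to 355 ± 25.2 CPM (-0.83 ± 0.16, adjusted p = 0.000942), with 37 of 46 DNA replication and E2F target genes (38 adjusted over the list alone, median -0.55, adjusted p = 4.09e-12; adjusted p = 0.337 with an estimated correlation). Of 30 mitosis genes 16 fell (19 adjusted over the list alone, median -0.45, adjusted p = 2.03e-06; adjusted p = 0.462 with an estimated correlation). Wound-associated epidermal genes went up (9 of 20 rose and 1 fell; 10 and 1 adjusted over the list alone; median 0.84, adjusted p = 0.0147; adjusted p = 0.462 with an estimated correlation). Neutrophil genes (9 of 14 rose, 11 adjusted over the list alone, median 1.76, adjusted p = 0.00015; adjusted p = 0.265 with an estimated correlation) and matrix-remodelling protease genes (5 of 13 rose, 6 adjusted over the list alone, adjusted p = 0.0147; adjusted p = 0.462 with an estimated correlation) did too. IL-17 and acute inflammation genes were split (4 of 12 rose and 2 fell; 8 and 2 adjusted over the list alone; median 1.38, adjusted p = 0.0403; adjusted p = 0.455 with an estimated correlation). Cd1d1 (-0.13 ± 0.31, adjusted p = 0.796) and Cdkn2a (-0.36 ± 0.38, adjusted p = 0.514) did not pass. In all, 2440 genes rose and 2388 fell. For 6807 genes (42%, 10% by chance) the libraries of the groups did not overlap.

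**Figure D3:**
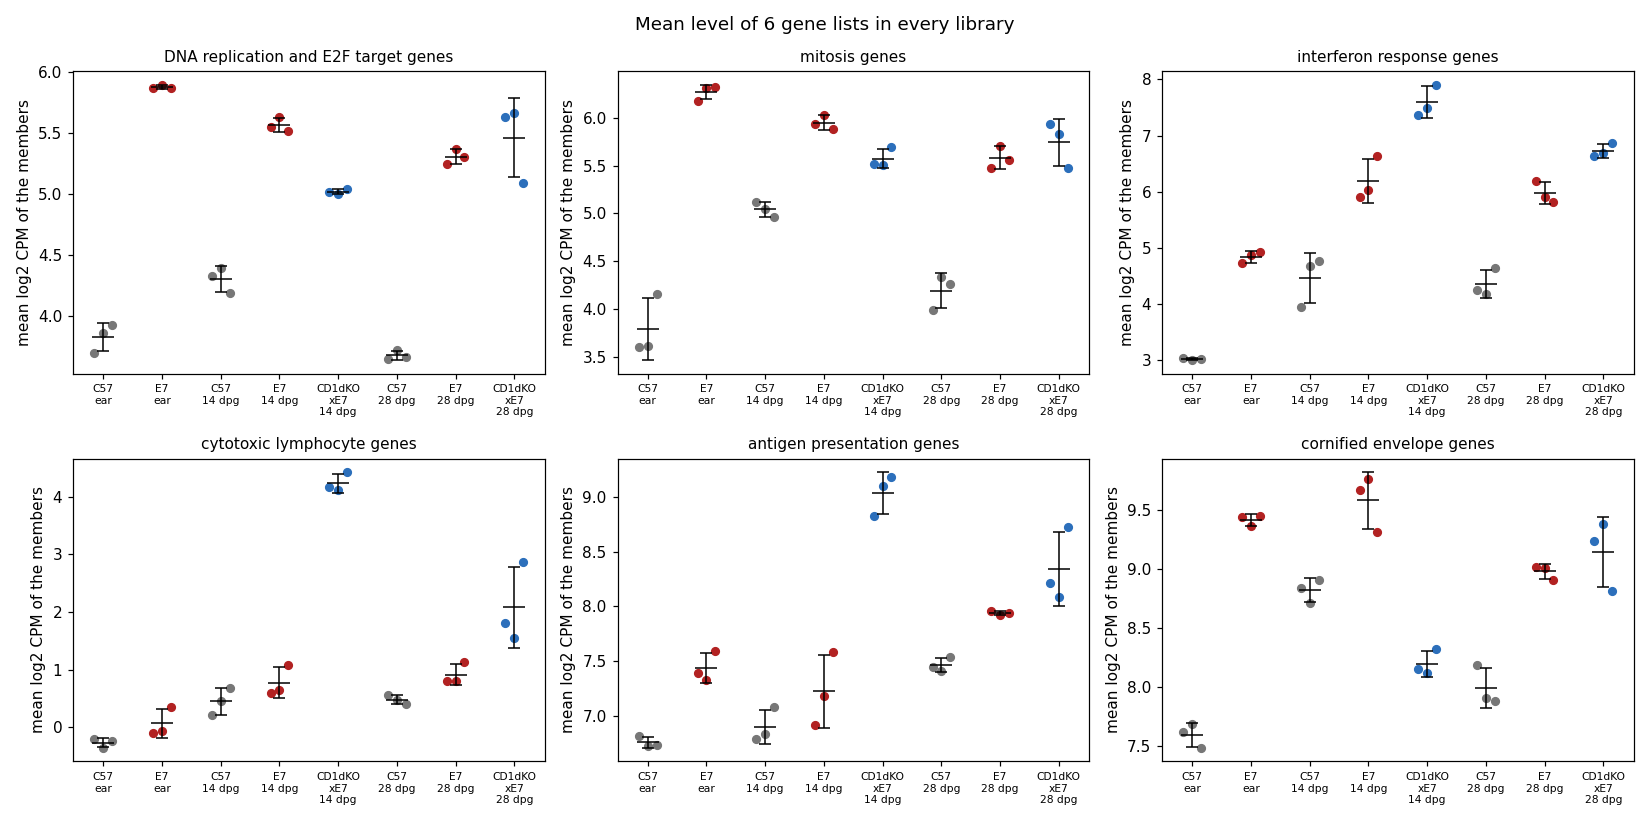
Mean log2 CPM of 6 gene lists in each library, by group, with points for libraries and bars for mean ± SD: DNA replication and E2F target, mitosis, interferon response, cytotoxic lymphocyte, antigen presentation and cornified envelope genes. Cytotoxic genes peak in CD1dKOxE7 grafts at 14 dpg, where cornified genes lie below those of E7 grafts.

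By 28 dpg few genes passed, but cytotoxic and interferon lists still separated the 2 groups. The cytotoxic list had come down to 2.08 ± 0.70 log2 CPM in CD1dKOxE7, against 0.91 ± 0.19 in E7 grafts. Icos rose (adjusted p = 0.0348). The interferon-induced genes Cxcl9 (7.92-fold, from 20.6 ± 10.3 to 167 ± 138 CPM, 2.99 ± 0.55, adjusted p = 0.047) and Gbp2b (8.12-fold, 3.02 ± 0.48, adjusted p = 0.0193) rose. At 14 dpg the log2 change was 4.36 for Cxcl9 and 3.02 for Gbp2b, so a constant donor difference stays open for Gbp2b. The lymphocyte gene Ms4a4b (2.83-fold), Aadacl4fm2 (7.24-fold) and Sprr2h (2.51-fold, from 51.0 ± 4.94 to 130 ± 4.96 CPM) rose too. Chrnb4 (6.15-fold, -2.62 ± 0.43), Rps3a1 (3.08-fold, -1.62 ± 0.29), Fgfbp3 (2.77-fold, from 59.1 ± 3.65 to 21.6 ± 0.442 CPM, adjusted p = 0.00303), Fgfr4 (2.73-fold), Ppp1r3e (2.40-fold) and Ang (2.06-fold) fell. As lists, cytotoxic lymphocyte genes (0 past the threshold over all genes and 13 of 16 rose adjusted over the list alone, median 1.42, adjusted p = 9.21e-15; adjusted p = 0.292 with an estimated correlation) and interferon response genes (1 and 15 of 32, median 0.57, adjusted p = 4.82e-21; adjusted p = 0.292 with an estimated correlation) were higher. T cell genes were too (1 and 8 of 17, median 0.70, adjusted p = 1.28e-07). So were immediate early and heat shock genes (0 and 4 of 15, median 0.48, adjusted p = 1.29e-06). Both lists had adjusted p = 0.451 with an estimated correlation. Mki67 (0.12 ± 0.16, adjusted p = 0.806), Ifng (2.65 ± 1.87 against 0.561 ± 0.186 CPM, 2.17 ± 0.63, adjusted p = 0.164), Cd1d1 (8.18 ± 5.65 against 23.4 ± 2.25 CPM, -1.55 ± 0.33, adjusted p = 0.0712), Ido1 (adjusted p = 0.692), Arg1 (adjusted p = 0.509) and Cdkn2a (adjusted p = 0.934) did not pass. Only 12 genes rose and 22 fell (35.3% higher, 57.3% of 241 with DESeq2). For 2675 genes (16.5%, 10% by chance) the libraries of the groups did not overlap. The call of Cxcl9 was lost with the replicate block (2.78, adjusted p = 0.0639), without a low count filter (0.0829; Rps3a1 0.0734) and with a filter of at least 1 CPM in at least 3 libraries (0.051), and that of Chrnb4 with DESeq2 (0.06). Without some 1 library the calls of Cxcl9 (adjusted p = 0.217 without E7 replicate 2), Chrnb4 (0.147 without CD1dKOxE7 replicate 1), Rps3a1, Ang, Fgfr4, Ppp1r3e, Gbp2b, Aadacl4fm2, Sprr2h and Ms4a4b ended. The 34 became 4, 5 and 8 without replicates 1, 2 and 3 of the E7 grafts, and 6, 57 and 304 without replicates 1, 2 and 3 of the CD1dKOxE7 grafts. With only the libraries of the 2 groups in the fit, 3 genes passed.

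Over both days, 1890 genes were higher and 1501 lower in CD1dKOxE7 than in E7 grafts (55.7% higher, 66.6% with no filter). Cd8b1 (14.2-fold, 3.83 ± 0.41), Cd8a (14.1-fold), Ubd (36.2-fold, 5.18 ± 0.62), Cxcl9 (12.8-fold, from 33.9 ± 18.0 to 582 ± 484 CPM), the histamine receptor gene Hrh4 (8.99-fold), Ifng (6.95-fold, 2.80 ± 0.41) and Ido1 (6.21-fold, 2.63 ± 0.84) rose. Ccnb1ip1 was at least 56.3-fold higher. Cd1d1 fell 1.79-fold (-0.84 ± 0.23, adjusted p = 0.0154), as did Mki67 (-0.36 ± 0.11, adjusted p = 0.0313), Rnf112 (4.24-fold), Erdr1 (4.03-fold), Gadl1 (3.45-fold), Fgfbp3 (2.74-fold), Edn3 (-1.35) and the elastic fibre gene Mfap4 (2.47-fold). Arg1 did not pass (adjusted p = 0.0634). The calls of Ido1 (adjusted p = 0.0543 to 0.0931) and Mki67 (0.0575 to 0.0742) were lost in 9 and 6 of the 12 fits without 1 library, and that of Mki67 with no filter (0.0522).

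The effect of the CD1dKO label itself differed between the days. It was smaller at 28 than at 14 dpg for Gzmb (-3.75 ± 0.49, adjusted p = 0.000463), Xcl1 (-2.90), Klrd1 (-2.03), Cd3d (-2.42 ± 0.36), Icos (-1.57 ± 0.26), H2-K1 (-1.22 ± 0.19), H2-Ab1 (-1.76 ± 0.28) and the acute phase gene Lcn2 (-3.99 ± 0.83, adjusted p = 0.00835). All 18 antigen presentation genes were lower in this difference, also adjusted over the list alone (median -1.39, adjusted p = 8.81e-23; adjusted p = 0.0766 with an estimated correlation). So were 14 of 17 T cell genes (16 adjusted over the list alone) and 11 of 16 cytotoxic lymphocyte genes (12 adjusted over the list alone), both with adjusted p = 0.0766 with an estimated correlation. Of 33 cornified envelope genes 27 were higher (30 adjusted over the list alone, median 1.68, adjusted p = 4.48e-39, and adjusted p = 0.0292 with an estimated correlation). These held Ivl (1.54 ± 0.19), Cdsn (1.40 ± 0.15) and Kprp (1.73 ± 0.18). Spink7 (5.96 ± 0.62), Krt2 (5.74 ± 1.35), Nmu (5.18 ± 0.44), the growth factor gene Ereg (3.61 ± 0.47) and Mki67 (0.94 ± 0.22, adjusted p = 0.0126) were higher. So were 28 of 46 DNA replication and E2F target genes (41 adjusted over the list alone, median 0.68, adjusted p = 2.51e-19; adjusted p = 0.229 with an estimated correlation). Ifng (-1.27 ± 0.91, adjusted p = 0.393) and Cd1d1 (-1.42 ± 0.45, adjusted p = 0.0517) did not pass. The 1059 genes higher and 1021 lower made 2080, which became 1240 without replicate 1 of the E7 grafts at 14 dpg and 1099, 1130 and 3956 without replicates 1, 2 and 3 of the CD1dKOxE7 grafts at 28 dpg.

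Genes changed between E7 and C57 grafts lay toward C57 in CD1dKOxE7 grafts of 14 dpg about as often as away from it, and at 28 dpg the share differed widely between libraries, with no test of a difference between the days. Of the E7 genes of 28 dpg (3345 higher and 2383 lower), 55.5% moved toward C57 in CD1dKOxE7 grafts of 14 dpg (51.9, 61.1 and 49.2% in single libraries), 65.5% of the higher and 41.5% of the lower ones. Of the higher ones 864 fell and 439 rose, and of the lower ones 238 rose and 380 fell. In the reverse pairing of days, 23.3% of the 4889 E7 genes of 14 dpg moved toward C57 in CD1dKOxE7 grafts of 28 dpg (14.6, 16.1 and 55.7% in single libraries, and 12% without replicate 3 of the CD1dKOxE7 grafts at 28 dpg). With genes called in ear, which share no library with the grafts, the shares were 59.6 and 27.1%. The CD1dKO effects of 14 and 28 dpg had a Pearson correlation of 0.325 over all genes.

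Against C57 grafts, CD1dKOxE7 grafts at 14 dpg held the largest interferon change among the pairs of groups compared. All 32 interferon response genes rose, also adjusted over the list alone (median 2.84, adjusted p = 3.94e-53, and adjusted p = 0.0179 with an estimated correlation), and of antigen presentation genes Tap1 rose 6.73-fold (2.75 ± 0.15) and Nlrc5 rose as well (2.39 ± 0.13). Ubd rose 388-fold (8.60 ± 1.10), Ifng 38.0-fold (5.25 ± 0.67), Gzmb 33.7-fold (5.08 ± 0.37) and Ido1 15.5-fold (3.96 ± 1.17; adjusted p = 0.0585 without C57 replicate 1). E7 was at least 157-fold, Trbv12-2 at least 52.1-fold, Ccnb1ip1 at least 30.2-fold and Il21 at least 26.6-fold higher, Il21 without a call under DESeq2 (adjusted p = 0.178). Krt2 fell 649-fold, from 5511 ± 2520 to 8.51 CPM (-9.34 ± 1.25), Krt24 45.4-fold, the Skint family gene Skint5 15.5-fold, Scgb1b27 at least 19.0-fold and the collagen gene Col1a1 3.10-fold, from 11401 to 3738 CPM. Sparc (-1.57 ± 0.27) and Col1a2 (-1.57 ± 0.29) fell, with 21 of 23 dermal matrix genes (22 adjusted over the list alone, adjusted p = 0.305 with an estimated correlation). Mki67 (0.36 ± 0.16, adjusted p = 0.0795) and Cdkn2a (adjusted p = 0.0809) did not pass, although 36 of 46 DNA replication and E2F target genes rose and 1 fell (41 and 1 adjusted over the list alone, adjusted p = 0.279 with an estimated correlation). In all, 3098 genes rose and 3249 fell. For 8417 genes (52%, 10% by chance) the libraries of the groups did not overlap.

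At 28 dpg CD1dKOxE7 grafts held more of proliferation, interferon and cytotoxic lymphocyte genes than C57 grafts. Mki67 rose 3.59-fold (1.84 ± 0.16, adjusted p = 5.54e-07), Cdkn2a rose (0.93 ± 0.37, adjusted p = 0.045; 0.59 and adjusted p = 0.165 without C57 replicate 2; 0.151 with only the groups compared in the fit), Mcm3 rose 5.16-fold, Mcm5 7.19-fold, Birc5 (1.75 ± 0.09) and Oas1a 8.11-fold. Chil4, E7 and Csta3 were at least 384-, 295- and 27.6-fold higher. All 46 DNA replication and E2F target genes (adjusted p = 0.0577 with an estimated correlation), all 30 mitosis genes (adjusted p = 0.0602 with an estimated correlation) and all 32 interferon response genes (adjusted p = 0.11 with an estimated correlation) rose, also adjusted over the list alone. Cytotoxic lymphocyte genes (13 of 16, 14 adjusted over the list alone, median 1.88, adjusted p = 0.000515; adjusted p = 0.477 with an estimated correlation) and T cell genes (8 of 17 rose and 1 fell, also adjusted over the list alone, median 0.86, adjusted p = 0.0142; adjusted p = 0.579 with an estimated correlation) were higher. Immediate early and heat shock genes rose (10 of 15, also adjusted over the list alone, adjusted p = 0.00087; adjusted p = 0.481 with an estimated correlation). Of 19 oxidative phosphorylation genes 18 rose (adjusted p = 0.183 with an estimated correlation), and all 10 Schwann cell genes fell (adjusted p = 0.183 with an estimated correlation), with Prx (-1.44 ± 0.22) and Gldn (-1.71 ± 0.27). Chrnb4 (35.9-fold, -5.16 ± 0.34), Krt24 (23.1-fold), myostatin (Mstn, 22.1-fold) and Cd1d1 (2.63-fold, -1.40 ± 0.33, adjusted p = 0.00285) fell, and Ifng stood at 2.65 against 0.0305 CPM. In all, 4335 genes rose and 3664 fell (54.2% higher, 43.9% under upper quartile normalization). For 8917 genes (55.1%, 10% by chance) the libraries of the groups did not overlap.

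Between 14 and 28 dpg, hair and wound genes fell and muscle genes rose in C57 grafts. Hair keratin genes fell, Krt33b 12.1-fold from 369 to 31.9 CPM (-3.60 ± 0.58), Krt34 from 359 to 27.2 CPM, Krt75 5.56-fold, Krtap19-1 46.5-fold and Krtap19-4 36.4-fold, with 25 of 27 hair follicle genes (26 adjusted over the list alone, median -2.90, adjusted p = 2.47e-19; adjusted p = 0.273 with an estimated correlation). Wound-associated epidermal genes fell (14 of 20; 17 fell and 1 rose adjusted over the list alone; median -2.33, adjusted p = 0.0329 with an estimated correlation). Csta3 was at least 27.4-fold lower, and Lce3a stood at 0.108 against 5.12 CPM, Sprr2i at 0.141 against 4.87 CPM and Sprr2f at 0.0305 against 3.56 CPM. Mki67 fell from 271 ± 30.1 to 128 ± 22.1 CPM (-1.13 ± 0.16, adjusted p = 0.000253), Cdk1 2.28-fold, Birc5 2.07-fold and Mcm5 2.43-fold, with 28 of 30 mitosis genes (29 adjusted over the list alone, adjusted p = 1.66e-29; adjusted p = 0.12 with an estimated correlation). Fast muscle genes rose, Mybpc2 24.6-fold from 3.57 to 88.4 CPM, Myh4 15.0-fold, Rpl3l 18.2-fold, parvalbumin (Pvalb) 13.2-fold and Eno3 5.28-fold, with 19 of 23 skeletal muscle genes (21 adjusted over the list alone, median 2.40, adjusted p = 6.54e-13; adjusted p = 0.342 with an estimated correlation). Scgb1a1 (23.5-fold) and Apobec2 (3.86) rose too, and Fosb (4.14 ± 1.18), which without replicate 1 of the 28 dpg grafts stood at 1.56 (adjusted p = 0.285; 0.124 with only the groups compared in the fit). Calls of Myh4 (adjusted p = 0.069 without 14 dpg replicate 1) and Csta3 (0.0533 without 28 dpg replicate 1) were lost too. Of 6 fits without 1 library, 5 ended the call of Sprr2i (adjusted p = 0.0566 to 0.0969) and 4 that of Sprr2f (0.0632 to 0.0809). In all, 1360 genes rose and 2301 fell (37.1% higher, 52.2% under upper quartile normalization). For 6778 genes (41.9%, 10% by chance) the libraries of the groups did not overlap.

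Hair genes fell in E7 grafts over the same time. Krtap19-4 fell 124-fold (-6.95 ± 0.97), Krtap16-3 78.3-fold, Krt33b 22.5-fold from 201 to 9.11 CPM and Krt81 19.3-fold, with 24 of 27 hair follicle genes (median -3.40, adjusted p = 6.21e-27; adjusted p = 0.207 with an estimated correlation). Crisp1 was at least 28.3-fold lower. Mki67 fell 1.51-fold (-0.59 ± 0.16, adjusted p = 0.0186; 0.0621 and 0.0674 without 14 dpg replicate 1 or 2, 0.0771 without 28 dpg replicate 1). Of 30 mitosis genes 12 fell (23 adjusted over the list alone, median -0.37, adjusted p = 1.95e-09; adjusted p = 0.514 with an estimated correlation), and of 46 DNA replication and E2F target genes 11 (11 adjusted over the list alone, adjusted p = 2.78e-06; adjusted p = 0.737 with an estimated correlation). Casp14 fell 3.98-fold from 1110 to 283 CPM and Arg1 4.87-fold, from 32.3 ± 21.2 to 6.75 ± 1.48 CPM (-2.29 ± 0.71, adjusted p = 0.0417; 0.0871 to 0.176 in 5 of the 6 fits without 1 library). Chil4 rose 86.7-fold to 33.1 ± 40.7 CPM (6.44 ± 1.23; adjusted p = 0.0567 with only the groups compared in the fit, and 0.063 for Arg1), Wfdc3 14.8-fold, H2-K1 1.74-fold and B2m (0.78), and Adra2c was at least 9.43-fold higher. Krt19 (17.9-fold) and the lipogenic gene Thrsp (16.1-fold) rested on replicate 1 of the 28 dpg grafts, without which their log2 changes were 1.76 (adjusted p = 0.36) and 2.03 (adjusted p = 0.272). Of 18 antigen presentation genes 11 rose (14 adjusted over the list alone, adjusted p = 0.337 with an estimated correlation). Of 10 type 2 cytokine genes 5 rose (7 adjusted over the list alone, median 1.35, adjusted p = 4.17e-06; adjusted p = 0.207 with an estimated correlation). In all, 1243 genes rose and 1535 fell, 2778 together. For 6382 genes (39.4%, 10% by chance) the libraries of the groups did not overlap. The count became 1211 and 1480 without replicates 1 and 2 of the 14 dpg grafts, and 1419 and 1422 without replicates 1 and 2 of the 28 dpg grafts.

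T cell and cytotoxic lymphocyte genes fell in CD1dKOxE7 grafts between the days. Gzmb fell 10.5-fold, from 53.8 to 5.10 CPM (-3.40 ± 0.31, adjusted p = 2.80e-05), Cd3d 4.67-fold, from 33.0 to 7.08 CPM (-2.22 ± 0.23), Icos 3.45-fold, Klrd1 (-2.15), Gzma (-2.01), Cd5 (-1.13) and Ifng 3.32-fold (-1.73 ± 0.46, adjusted p = 0.013; up to 0.0694 without 14 dpg replicate 3 or 28 dpg replicate 1 or 2). Of 17 T cell genes 15 fell, and of 16 cytotoxic lymphocyte genes 15 (16 adjusted over the list alone), and both lists kept adjusted p = 0.0446 with an estimated correlation. Neutrophil genes fell as well (9 of 14, also adjusted over the list alone, median -1.46, adjusted p = 1.16e-05; adjusted p = 0.185 with an estimated correlation). S100a8 fell 46.0-fold from 780 ± 275 to 17.1 ± 13.1 CPM, S100a9 42.7-fold from 909 to 21.5 CPM, and Arg1 fell 5.61-fold (-2.49 ± 0.65, adjusted p = 0.0141; up to 0.0756 without the same 3 libraries). Immediate early and heat shock genes rose (6 of 15, also adjusted over the list alone, median 0.50, adjusted p = 0.00243; adjusted p = 0.49 with an estimated correlation). Antigen presentation genes fell (15 of 18, 17 adjusted over the list alone, adjusted p = 0.341 with an estimated correlation), with Tapbp (-0.83) and Ciita (-1.05). Krtap19-5 (48.1-fold), Krt34 (14.1-fold) and Krt81 (11.5-fold) fell, and Crisp1 stood at 0.0367 against 4.45 CPM. Cornified envelope genes rose (23 of 33, 1 fell; median 0.93, adjusted p = 5.27e-20; adjusted p = 0.0582 with an estimated correlation). Krt2 rose 68.7-fold, from 8.51 to 592 ± 496 CPM (6.10 ± 1.11), the antibody gene Ighg1 62.0-fold (5.95 ± 1.32), Pyy 34.1-fold and Serpinb6d 15.7-fold, and Scgb1b27 stood at 1.44 ± 0.117 CPM against 0 counts. Calls of Ighg1 (adjusted p = 0.0871), Ciita (0.0792), Ifng (0.0799) and Arg1 (0.0835) ended when only the groups compared were in the fit. Mki67 did not pass (0.35 ± 0.16, adjusted p = 0.122). In all, 1747 genes rose and 1913 fell, 3660 together. For 4998 genes (30.9%, 10% by chance) the libraries of the groups did not overlap. Without replicates 1 and 2 of the 28 dpg grafts the count became 2264 and 2022.

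The E7 effect in grafts itself differed between the days for 27 genes, 24 higher and 3 lower at 28 dpg (88.9% higher, 55.5% of 155 with DESeq2). Those higher at 28 dpg included the stefin genes Stfa2 (4.01 ± 0.71, adjusted p = 0.0383) and Stfa3 (2.48 ± 0.43), Cstdc5 (3.66 ± 0.49), Cstdc6 (3.63), and the wound keratin gene Krt16 (3.88 ± 0.41, adjusted p = 0.000862), Lpo (3.46 ± 0.53) and Tex15 (2.76). The growth factor gene Btc (-2.27 ± 0.26, adjusted p = 0.0013), Elovl1 (-0.70 ± 0.13) and Ralgapa2 (-0.61 ± 0.11) were lower. With the replicate block Stfa2, Stfa3 and Ralgapa2 lost their calls (adjusted p = 0.0599), and in 8, 9 and 11 of the 12 fits without 1 library they did so too, as did Elovl1 in 10, Tex15 in 6, Cstdc6 in 3 and Lpo in 2. Of 30 mitosis genes 1 was higher, and 19 adjusted over the list alone (median 0.62, adjusted p = 8.32e-19; adjusted p = 0.265 with an estimated correlation), while Mki67 itself did not pass (0.54 ± 0.22, adjusted p = 0.467). The count of 27 became 17 without replicate 1 of the C57 grafts at 14 dpg, 12 without replicate 3 of the C57 grafts at 28 dpg, 72 without replicate 3 of the E7 grafts at 14 dpg, and 15, 17 and 15 without replicates 1, 2 and 3 of the E7 grafts at 28 dpg. It became 96 without replicate 3 of the CD1dKOxE7 grafts at 28 dpg, a setting chosen after the data were seen.

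**Figure D4:**
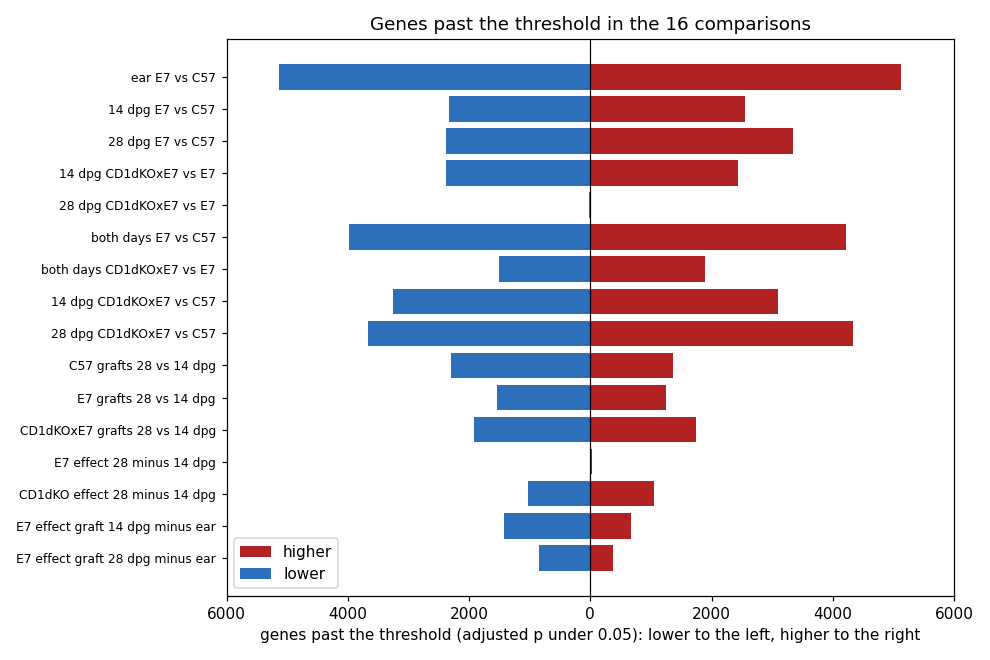
Number of genes past adjusted p < 0.05 in each of the 16 comparisons, higher to the right and lower to the left of 0. CD1dKOxE7 and E7 grafts differed in 4828 genes at 14 dpg and in 34 at 28 dpg.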

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

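The comparisons, gene lists, settings, rules for singling out results and regroupings of libraries were chosen before the data were examined. The tests of explanations in this part were chosen only after the result was seen, as tests, not predictions; those within 5 Mb of Cd1d1 and in the chromosome 14 interval, which was drawn from the 28 dpg genes, were set after these genes and before their 14 dpg values were seen.

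CD1dKOxE7 and E7 grafts differed in 4828 genes at 14 dpg and in 34 at 28 dpg, and the test of the difference between days gave 2080 genes, 1059 higher and 1021 lower. A difference between flow cell lanes would give the same change at both days, which these 2080 genes argue against. The library that stands apart, CD1dKOxE7 28 dpg replicate 3, does not account for it, since without it 304 genes passed at 28 dpg, against at least 3814 at 14 dpg without any 1 CD1dKOxE7 library. A larger share of recipient trunk tissue in the 14 dpg CD1dKOxE7 grafts was taken to raise trunk Hox genes about as much as T cell genes. The median log2 fold change was 0.19 for trunk Hox genes (quartiles -0.03 and 0.59) and 2.48 for T cell genes. This argues only against trunk tissue that brings both sets of genes along. Recipient immune cells need not carry Hox transcript, so the test cannot decide on them, and the T cell value came from the same comparison. The donor genotype remains open as the cause, untested apart from lane, and a biological difference is a hypothesis only.

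Cd1d1 was read in all 6 libraries labelled CD1dKOxE7. For a C57 or E7 graft among them, genes at least 2-fold apart between the other 5 and the 12 C57 and E7 grafts were chosen without the library tested. All lay on the side of the other 5 (lowest share 1, exact binomial p of at most 2.07e-07 if genes were independent). Of the 6 libraries, 5 had only 6 such genes, under the 10 first asked for. The 6 libraries were run on another lane than the 12, so these genes may mark lane. They argue against a graft from the lane of the 12, but cannot exclude a C57 or E7 graft run on the lane of the 6. A wrong label from outside these grafts was not tested. RNA of recipient cells that carry the gene stays open. Over the 6 libraries Cd1d1 followed trunk Hox genes (Spearman rho 0.657, exact p = 0.175 over 720 permutations). Pearson was 0.857 (exact p = 0.0347), and 0.763 without the 2 farthest libraries. Cd1d1 followed macrophage genes as well (Pearson 0.934, exact p = 0.025; 0.517 without the 2 farthest). Reads from a part of the gene that the deletion left stay open too, with a lowest count of 34, because counts per gene do not show the part.

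The 33 placed genes among the 34 of 28 dpg held 5 on chromosome 3, where Cd1d1 lies (1.71 by chance), and 6 on chromosome 14 (1.13 by chance). For chromosome 3, Fisher exact p was 0.026 (0.2734 adjusted over the chromosomes), so chance placement stays open. Chromosome 14 passed (adjusted exact p = 0.0165), its 6 genes lower at both days. On chromosome 3, Rps3a1 (start 86137940) and Arhgef11 (start 87617548) fell at both days. Gbp2b and 1810037I17Rik rose at both, and Sprr2h at 28 dpg only. Strain variants linked to the targeted locus or in the chromosome 14 interval stay open. At 14 dpg, 47 of 147 genes within 5 Mb of Cd1d1 passed (32%, Fisher exact p = 0.652). In the interval 64 of 217 did (29.5%, Fisher exact p = 0.882). With 30.1% of genes past the threshold elsewhere, neither share can show a variant that acts on few genes. Ccnb1ip1, read in CD1dKOxE7 grafts but no other graft (described below), lies in this interval. The donor genotypes themselves differ and were not tested apart from these.

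The test of the difference between days for E7 against C57 grafts gave 27 genes, in fitted log2 values Stfa2 (4.01), Krt16 (3.88), Cstdc5 (3.66), Btc (-2.27), Elovl1 (-0.70) and Ralgapa2 (-0.61) among them. The test of the difference between days for CD1dKOxE7 against E7 grafts gave Spink7 (5.96), Krt2 (5.74), Nmu (5.18), Mki67 (0.94), Ccl1 (-6.87), Krt19 (-6.00) and Reg3g (-4.74). The test of the difference between 14 dpg grafts and ear for E7 against C57 gave 2098 genes, with Lypd2 (3.91), Lhfpl3 (3.57), Fbp2 (3.47), Reg3g (-8.18), Cxcl13 (-7.42), Cxcl2 (-6.78), Cdkn2a (-4.79) and Mki67 (-1.87). The test of the difference between 28 dpg grafts and ear gave 1234 genes, with Fcer2a (4.13), Ifitm6 (3.72), Myod1 (3.32), Acod1 (-7.39), Crnn (-6.18), Cxcl2 (-5.70), Cdkn2a (-5.09) and Mki67 (-1.34). Fitted values of Ccl1, Reg3g, Lypd2 and Acod1 depend on the prior count, since a group of each had 1 to 3 counts. Without E7 28 dpg replicate 3 the Reg3g value between days became -1.72 (adjusted p = 0.654), and without E7 28 dpg replicate 1 that of Krt19 became -3.60 (adjusted p = 0.136) and that of Fcer2a against ear 2.47 (adjusted p = 0.191). Between 28 dpg grafts and ear, leaving out 1 of 12 libraries ended the calls of Ifitm6 (adjusted p up to 0.093) and Myod1 (up to 0.0994) in 10 fits each and those of Fcer2a and Acod1 in 8 each, and without C57 28 dpg replicate 1 Acod1 became -5.91 (adjusted p = 0.0998) and Cxcl2 -4.08 (adjusted p = 0.0978). Between 14 dpg grafts and ear Lhfpl3 lost its call in 7 of 12 fits (adjusted p = 0.0522 to 0.138), with 3.07 without E7 14 dpg replicate 3.

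Other splits of the same libraries were counted beside each number of genes. With 3 libraries against 3 there were 10 splits, too few for a share under 0.05, and the real split was the 1 with the highest count in each: ear 10267 (highest other 0), E7 against C57 4889 (0) at 14 dpg and 3345 higher with 2383 lower (0) at 28 dpg, CD1dKOxE7 against E7 4828 (1) and 34 (1), CD1dKOxE7 against C57 6347 (0) and 7999 (0), and the later against the earlier day in C57 3661 (1), E7 2778 (0) and CD1dKOxE7 grafts 3660 (121). Of 25 splits drawn from 200, only the real 1 gave as many for both days of E7 against C57 (8197, highest other 9). The same held for both days of CD1dKOxE7 against E7 (3391, highest other 1363), so chance splits were excluded at a share under 0.05. For differences between days, 3 of 25 splits gave as many for E7 (27, highest other 2328) and CD1dKOxE7 (2080, highest other 3284). Between grafts and ear it was 1 at 14 dpg (2098, highest other 20) and 4 at 28 dpg (1234, highest other 7471). Such splits cannot test a change of the donor difference. Those that broke the labels of both sides gave 0 genes. All as-large others kept those of 1 day or tissue, and so its donor difference.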

How the results depend on the processing

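The setting without CD1dKOxE7 28 dpg replicate 3 in comparisons that do not use it was chosen after seeing the data; all others were chosen before. Of 6042 values of named genes past the threshold, recomputed under the alternatives, 5661 kept their direction and side of the threshold, 381 kept direction only and 0 reversed; 313 of 392 named results kept both under every alternative run, and 22 named results not past it passed under an alternative. Medians of lists changed sign in 12 of 1088 cases under RLE or upper quartile normalization. Depth limits genes under 0.217 to 0.458 CPM in a library (3 counts).

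With a log2 fold change of at least 1 also required, fewer genes pass by construction: ear 3363; E7 against C57 887 (14 dpg), 1339 (28 dpg), 1158 (both); CD1dKOxE7 against E7 1489, 16, 680; CD1dKOxE7 against C57 2206, 2463; 28 against 14 dpg 1014 (C57), 684 (E7), 1269 (CD1dKOxE7); differences between days 16 (E7) and 823 (CD1dKO); graft minus ear 827 (14 dpg) and 372 (28 dpg). With DESeq2 the 34 genes of CD1dKOxE7 against E7 at 28 dpg became 241 and the 27 of the E7 difference between days 155. With only the groups compared in the fit these became 3 and 55, CD1dKOxE7 28 against 14 dpg 1308 and the CD1dKO difference between days 1314. With the replicate block the 34 became 65. The cause was not tested for DESeq2, the groups in the fit and the replicate block; the block was not run for ear or graft minus ear.

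With an estimated correlation the lists past the threshold fell to 1 in ear; 0, 3 and 1 for E7 against C57 (14 dpg, 28 dpg, both); 6, 0 and 5 for CD1dKOxE7 against E7; 6 and 0 for CD1dKOxE7 against C57; 1, 0 and 4 for 28 against 14 dpg (C57, E7, CD1dKOxE7); 0 and 1 for the differences between days; and 3 and 0 for graft minus ear, since it widens each list's error. Under fry 0 passed for CD1dKOxE7 against E7 at 28 dpg, 8 for E7 28 against 14 dpg, 0 and 13 for the differences between days and 8 for 28 dpg graft minus ear; the cause was not tested. With genes of at least 10 CPM the ear and graft correlations were 0.781 (14 dpg) and 0.871 (28 dpg), which leaves out genes with the largest counting error.

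Leaving out 1 library at a time, which leaves fewer samples, gave 3043 (without C57 14 dpg replicate 3) to 5694 genes for E7 against C57 at 14 dpg, and 4 (without E7 28 dpg replicate 1) to 304 (without CD1dKOxE7 28 dpg replicate 3) for CD1dKOxE7 against E7 at 28 dpg. It gave 1211 to 3624 for E7 and 2022 to 5142 for CD1dKOxE7 28 against 14 dpg, 12 to 96 and 1099 to 3956 for the E7 and CD1dKO differences between days, and 1394 to 2685 and 743 to 1730 for graft minus ear at 14 and 28 dpg. The correlations of ear and graft were 0.679 to 0.730 (14 dpg) and 0.817 to 0.835 (28 dpg). The highest of the gene counts were all without CD1dKOxE7 28 dpg replicate 3, the library that stands apart.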

Other observations

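Most listed Hox genes of the trunk were higher in grafts than in ear skin. Hoxc8 had 0 counts in all 6 ear libraries and 2.37 to 15.5 CPM in the 18 graft libraries, and 13 of 19 trunk Hox genes were higher in every graft than in every ear library. As a mean over the list, C57 ear stood at -1.29 and E7 ear at -1.20 log2 CPM, against 0.88 to 1.95 in the graft groups. This list and its test were chosen after the values were seen, and tissue was not separated from flow cell. Among the 28 dpg CD1dKOxE7 grafts, replicate 3 held the highest list mean (2.04, against 0.57 and 0.04) and Hoxc8 at 14.8 CPM, against 3.6 and 4.2 CPM.

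Ccnb1ip1 (chromosome 14, 50789249 to 50795728) had 0 counts in all C57 and E7 grafts and stood at 4.14 ± 2.14 CPM at 14 dpg and 3.09 ± 0.666 CPM at 28 dpg in CD1dKOxE7 grafts. In ear it stood at 0.0235 CPM (C57) and 0.0315 CPM (E7). The predicted gene 1810037I17Rik (chromosome 3, 122924397 to 122926194), outside the named rule and chosen after its values were seen, separated the same libraries at both days (log2 fold change 2.88 at 14 dpg and 2.82 ± 0.167 at 28 dpg). Over the 6 CD1dKOxE7 and 12 other grafts, 272 genes lay higher and 73 lower in every CD1dKOxE7 graft, against 0.87 expected by chance in each direction.

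Zbtb16, which encodes a transcription factor of NKT cells and other cells, stood at 33.5 CPM in C57 ear and 8.64 CPM in E7 ear, while NKT cell-associated genes as a list did not pass there.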
